A study of Arabidopsis thaliana with 12 samples.

How the data were processed

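The values came from 1 table of the whole series, with a column per sample. The deposited values were intensities on a linear scale, never below 0, with column means between 1.01 and 1.07. The scanner, background correction, scaling and probe layout used by the authors are not given in the sources used here, so it is not known how the deposited zeros arose. Of 3439 probes 3437 had values. The platform annotation gave 1 gene symbol for 692 of these probes and several for 869, and 1876 had no entry. Symbols were updated through gene identifiers to the RefSeq gene table of the Columbia assembly TAIR10.1, in which 690 of the 692 were found. Probes with several genes or no entry were tested as features and not named. STN7, STN8 and TAP38 were on none of the probes with an entry, those with several genes included, and probes without an entry could not be assigned to genes here, so the mutated gene was not analysed here and did not check the labels.

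Column medians differed by up to 0.478 log2, over the limit of 0.1 fixed before the data were examined, so arrays were quantile-normalized. Normalized intensities under their 10th percentile (0.0702, or -3.83 log2) were set to it before log2, and 188 probes at this floor in all 12 samples were left out. The 1 locus with 2 probes was represented by their log2 mean, which left 3248 features. The floor was set after the values had been seen. A grid of 3 scalings and 3 floors, run first, gave between 404 and 532 calls over its 9 settings with averaged samples and between 1164 and 1466 without averaging.

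Samples were grouped by title. All 12 samples had their highest correlation of deviations from the group mean with the sample of the consecutive number, between 0.188 and 0.632, against at most 0.146 with any other sample. Spearman correlations of such samples lay between 0.957 and 0.986, but those of other samples of a group reached 0.977, so they do not set such samples apart. The plan allowed nearly identical samples of a group to be averaged, and the decision that these were such samples was made from the values. It moved the count of calls from 1283 with 12 separate samples to 494.

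Each feature was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a replicate block, with two-sided p-values adjusted by the Benjamini-Hochberg method and called under 0.05. Gene lists with at least 4 measured members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry. The text names the 12 genes with the largest rise and the 12 with the largest fall among called genes above the lowest 25% by mean level, and up to 4 members of each list with the smallest p. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

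The dependence on the probe number was found after the data had been seen. The cycle of 288 came from a scan of 800 lags, where the Spearman correlation of differences was highest at 288 (0.43) and at 1 (0.42). The set width of 6 came from a scan of 11 widths. Widths of 2, 3 and 6 accounted for 37.2%, 37.3% and 36.9% of the variance of the differences, so the scan did not single out 6. In set centring, the median deviation of each set from the probe means was subtracted in each sample. Before it was chosen, 6 sizes of a window of neighbouring probes had been tried, and all 6 are given with the alternatives.

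The fit was tested on simulated data for the stn7 against WT comparison, with 3248 features drawn from the measured means and spreads and 200 of them changed, over 10 draws. It recovered 16.0% of 1.5-fold, 55.4% of 2-fold and 79.7% of 3-fold changes, and 4.56% of its calls were false. With the measured set medians added to these changes, 59.5% of the calls were false without set centring and 5.75% with it. The centring used the same sets to which the medians had been added, so it was bound to remove them. Simulated replicates varied independently in each feature, unlike the measured ones, so these false shares do not carry over to the measured calls. With the set medians alone and no changed genes, 2.3 features on average were called without set centring, while beside the 200 changed features 181 were called in error. The simulated spreads already hold the set deviations of the measured replicates, and noise was independent in each feature. The 2.3 therefore does not carry over to the measured calls either. A simulated list of 7 independent genes shifted by 0.5 log2 was called by camera in 100% of 100 draws, and in 1% with no shift. No other simulated feature differed between the groups, whereas 1051 of the 3248 measured features had an unadjusted limma p under 0.05. Camera compares a list with the other features, so the 100% does not carry over to the measured lists.

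Alternatives fixed before the data were examined covered scaling, a filter on dim probes, a replicate block, the variance model, the choice of probe, each sample left out and the source names. Those added after the data had been seen covered the averaging of samples, the floor, cyclic loess, each averaged replicate left out and the centring by probe number.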

Results

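The series measured transcript levels in Arabidopsis thaliana of the Columbia ecotype with 1-channel arrays, in 6 samples titled as the stn7 mutant and 6 titled as wild type (WT). STN7 is the thylakoid protein kinase that phosphorylates the light-harvesting antenna of photosystem II in state transitions, the short-term balancing of excitation between both photosystems. Each array gave a relative intensity for 3437 probes, with a median between 0.297 and 0.369 in the WT samples and between 0.354 and 0.414 in the stn7 samples. Between 4.66% and 6.58% of the values of a sample were exactly 0. In each group samples 1 and 2, 3 and 4, and 5 and 6 deviated together from their group mean. Each such pair was averaged and counted as 1 replicate, which left 3 replicates per group, and this number limits the precision. The labels do not say whether replicates came from separate plants, so p-values measure only the spread between these samples. Of the 6 samples titled stn7, 5, all but sample 1, carried the source name of the WT, and samples were grouped by title. The averaged stn7 samples 1 and 2 therefore carried different source names.

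The comparison asked which transcripts differ between the mutant and the WT. Among photosystem II subunits, PSB27, an assembly factor of the complex, fell by 0.81 on the log2 scale in stn7 (SE 0.19, n = 3 per group, adjusted p = 0.0317). The mean level was 1.75-fold lower, and all 3 stn7 replicates lay below all 3 WT replicates, which its choice by smallest p favours. With the replicate block PSB27 missed the threshold (limma, adjusted p = 0.0503). In pigment synthesis, Z-ISO, the zeta-carotene isomerase of carotenoid synthesis, rose 2.04-fold (log2 difference 1.03, SE 0.21, adjusted p = 0.0246). APS4, an ATP sulfurylase of sulfate assimilation, fell 1.87-fold, and FBN2 (AT2G35490), a plastoglobule-associated fibrillin, fell 1.59-fold. In the values as deposited neither APS4 (-0.71 log2) nor FBN2 (-0.44 log2) passed. FBN2 also did not pass without WT sample 4 (-0.64 log2) or without stn7 sample 3 (-0.62 log2), against -0.67 log2 with all samples. With the replicate block FBN2 missed the threshold too (limma, adjusted p = 0.0589). The pentatricopeptide repeat genes AT2G17670 and AT3G26630, members of a family that acts in organellar RNA processing, went opposite ways. AT2G17670 rose 2.13-fold and AT3G26630 fell 2.61-fold. After the centring by probe number described with the array-wide counts, only AT3G26630 of this pair passed (-1.14 log2), with AT2G17670 at 0.52 log2 against 1.09 before. FBN2 did not pass after this centring either (-0.50 log2), while PSB27, Z-ISO and APS4 did.

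Across the array 494 of 3248 features passed an adjusted p of 0.05 in limma, of which 212 were higher and 282 lower in stn7. At a difference of at least 2-fold 162 features passed, 47 higher and 115 lower. Of the 650 features with a single gene name, 108 passed, 48 higher and 60 lower. The split between higher and lower depended on the scaling. The deposited values gave 289 higher and 179 lower, and arrays centred on their median gave 133 higher and 347 lower. At 2-fold these were 105 higher and 72 lower in the deposited values, and 27 higher and 168 lower with median centring. The median difference over all features was 0.05 log2 after quantile normalization, 0.19 in the deposited values and -0.03 after median centring. Leaving out 1 averaged replicate lowered the count of 494 to between 4 (without stn7 replicate 1) and 284 (without stn7 replicate 2). Of the 61 genes followed by name 29 passed with all replicates, and none of the 29 passed without stn7 replicate 1. That replicate holds stn7 sample 1, the only sample titled stn7 that does not carry the source name of the WT. The loss does not rest on sample 1 alone. With only sample 1 left out and sample 2 kept, 419 features passed, 407 of them shared in the same direction with the 494. In that fit 4 of the 29 genes missed the threshold. Without another of the averaged replicates, between 9 (without stn7 replicate 2) and 27 (without WT replicate 2) of the 29 missed the threshold. AT3G09080 and AT3G26630 passed in 5 of the 6 cases, PSB27, Z-ISO and APS4 in 1, and FBN2, PIFI and CSLA01 in 0. A fit with fewer replicates has less power, but all 6 fits had the same number of replicates, so this does not account for the range between them.

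The differences followed the probe number, and this bears on every gene named here. In 48 sets of probe numbers that recur along a cycle of 288 numbers, the median stn7 minus WT difference ran from -0.62 to 0.62 log2. The 5 sets with a median above 0.4 held 97 features called higher and 0 called lower, and the 4 sets below -0.4 held 80 called lower and 0 called higher. The sets accounted for 36.9% of the variance of the differences (adjusted r2). They also accounted for 44.2%, 13.9% and 42.3% of the variance of the deviations of the 3 WT replicates from their own mean, and for 23.4%, 10.9% and 4.73% in the 3 stn7 replicates. In the 5 sets above 0.4 no WT replicate had a median more than 0.092 from the WT mean, while an stn7 replicate lay up to 0.449 from the stn7 mean. In the 4 sets below -0.4 these values were 0.454 and 0.108. With each sample centred within the sets, 182 features passed, 57 higher and 125 lower. Of the 494 features, 152 passed again in the same direction, 36 higher and 116 lower. Set centring was chosen after the data had been seen, and not every such correction lowered the count: centring each probe on its near neighbours gave between 215 and 589 calls over 6 window sizes. Of the 589 and the 550 of the next window, 274 and 293 were shared in the same direction with the 494, and at 2-fold all 6 windows gave fewer calls, 65 to 86 against 162.

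**Figure D1:**
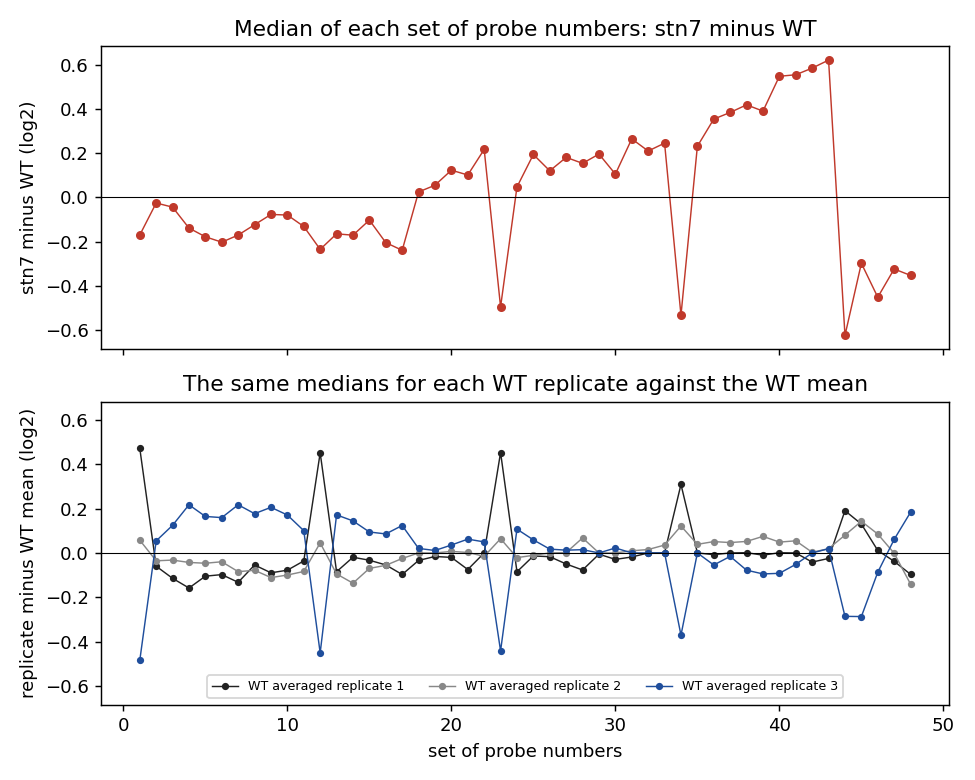
Upper panel: median log2 difference, stn7 minus WT, of the probes in each of the 48 sets of probe numbers, from -0.62 to 0.62. Lower panel: median log2 deviation of each of the 3 averaged WT replicates from the WT mean in the same sets, where replicates 1 and 3 deviated in opposite directions in sets 1, 12, 23 and 34.

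The 12 named genes with the largest rises went up 1.90-fold to 2.22-fold, with adjusted p between 0.0114 and 0.0347. AT4G38670 rose 2.22-fold (log2 difference 1.15, SE 0.19, n = 3 per group), AT5G56850 2.17-fold and AT2G36920 2.09-fold. AT1G55440, AT1G74070, Z-ISO, AT3G20680, AT5G19750, AT5G17280, AT5G11550, AT3G15140 and AT2G17670 made up the rest. In each of the 12 genes all 3 stn7 replicates lay above all 3 WT replicates, which the choice of these genes by rise and adjusted p favours. After set centring only AT1G74070 (0.63 log2, adjusted p = 0.0283), Z-ISO (1.18 log2, adjusted p = 0.0264) and AT5G11550 (0.76 log2, adjusted p = 0.0202) passed again. AT5G19750 did not pass with arrays centred on their median (0.79 log2) or without stn7 sample 1 (1.01 log2). AT3G20680 did not pass with the replicate block (limma, adjusted p = 0.0593). The 9 genes that did not pass after set centring had set-centred differences between 0.42 and 0.58 log2, against 0.92 to 1.15 before it. That of AT4G38670 was 0.58 log2, with an adjusted p of 0.0687.

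The 12 named genes with the largest falls went down 2.11-fold to 3.12-fold, with adjusted p between 0.00550 and 0.0481. AT3G09080 fell 3.12-fold (log2 difference -1.64, SE 0.17, n = 3 per group), and MAMI, named for a membrane-associated mannitol-induced protein, fell 2.85-fold. AT4G25290 fell 2.68-fold, AT3G26630 2.61-fold, AT2G36480 2.56-fold, AT4G27510 2.49-fold and AT2G04790 2.37-fold. The chromatin remodelling gene chr31 fell 2.13-fold. These 8 genes passed again after set centring, with AT3G09080 at -1.49 log2 (adjusted p = 0.00341) and AT3G26630 at -1.14 log2 (adjusted p = 0.00752). MAMI went from -1.51 to -1.01 log2, and AT2G04790 from -1.25 to -0.66 log2 (adjusted p = 0.0492). AT2G25830, AT2G26110, AT4G38040 and CSLA01, a cellulose synthase-like gene, fell 2.60-fold, 2.59-fold, 2.37-fold and 2.11-fold, and none of these 4 passed after set centring. In AT2G25830 1 of the 6 stn7 samples lay at the floor, which limits its fold. Their set-centred differences were -0.92 log2 (SE 0.30), -0.72 (SE 0.27), -0.88 (SE 0.30) and -0.87 (SE 0.23), against -1.38 (SE 0.31), -1.37 (SE 0.38), -1.24 (SE 0.28) and -1.08 (SE 0.27) before it. In the values as deposited AT2G26110 (-1.28 log2) and CSLA01 (-0.88 log2) did not pass either. With the replicate block AT2G26110 and CSLA01 missed the threshold as well (limma, adjusted p = 0.0811 and 0.0664). With 1 sample left out, AT2G26110 missed the threshold in 9 of 12 cases, with differences between -1.31 and -1.42 log2 and adjusted p between 0.0504 and 0.0728. So did AT2G25830 without stn7 sample 1 (-1.29 log2), AT4G38040 without stn7 sample 5 (-1.45 log2), and CSLA01 without stn7 sample 1, 3 or 6 (-1.03, -1.05 and -1.19 log2).

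**Figure D2:**
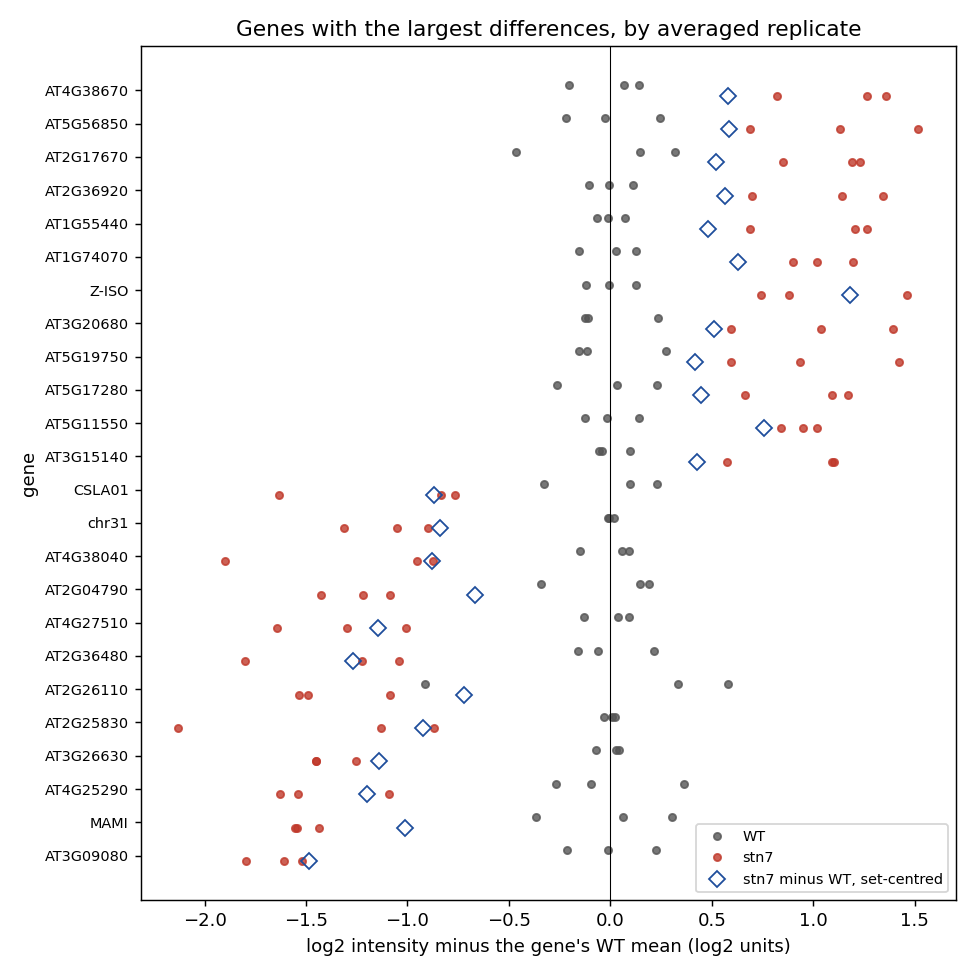
Log2 intensity of each averaged replicate minus the WT mean of that gene, for the 12 genes with the largest rises and the 12 with the largest falls. Grey points are the 3 WT replicates, red points the 3 stn7 replicates, and open diamonds the stn7 minus WT difference after set centring, which for AT4G38670 was 0.58 against 1.15 without it.

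Of 31 gene lists fixed before the data were examined, 26 had no member among the features with a single gene name and 5 had between 1 and 3. None therefore reached the 4 members needed for a set test. Members on probes with several genes or without an entry were not counted, so the array may carry more of them. The lists of plastid-encoded and mitochondrion-encoded genes, among the 26, held no gene at all. The root, seed and senescence markers were among the 26, so other tissues were not checked for. Among photosystem II subunits PSB27 passed, both over all features and adjusted over the list alone, while PSBY (0.46 log2, SE 0.27) and PSBW (-0.00 log2, SE 0.14) did not. The value of PSBW depended on the scaling, with -0.43 log2 in the deposited values and -0.66 log2 with median centring, where it did not pass either. LHB1B2, which encodes an LHCII antenna protein, differed by 0.12 log2 (SE 0.17) and the photosystem I gene PSAN by 0.38 log2 (SE 0.25), but LHB1B2 was at -0.06 log2 in the deposited values and -0.29 log2 with median centring, and PSAN at 0.23 and -0.00 log2. The Calvin cycle genes PRK (-0.30 log2, SE 0.19) and SBPASE (0.38 log2, SE 0.28) and the chlorophyll synthesis genes CHLM (0.46 log2, SE 0.19) and CHLP (-0.05 log2, SE 0.19) did not pass, nor did any of these 6 adjusted over the list alone. PSB27 passed again after set centring (-0.66 log2, adjusted p = 0.0329), but not with the replicate block (adjusted p = 0.0503).

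A further 9 lists were drawn up after the annotation had been read, before any result per gene was seen. Photosynthesis genes had 7 measured members, of which 1 fell (PSB27). Of 5 pigment synthesis genes 1 rose (Z-ISO), of 5 fibrillins 1 fell (FBN2), and of 8 genes of amino acid, vitamin and carbon metabolism 1 fell (APS4). Of 10 genes of the NDH complex and thylakoid assembly 1 rose, PIFI (0.56 log2, SE 0.15, adjusted p = 0.0466), and of 6 mTERF genes, a family of organellar nucleic acid-binding proteins, 1 rose, AT5G55580 (0.81 log2, SE 0.15, adjusted p = 0.0188). Of 18 pentatricopeptide repeat genes 1 rose and 1 fell. None of 6 plastid redox enzymes or 4 plastid ribosomal proteins passed. Adjusted over the list alone PIFI did not pass (0.0657), while the sucrose phosphate synthase gene SPS4F (-0.57 log2, 0.0353) and the fibrillin gene FBN5 (0.47 log2, 0.0445) did, and the other called members passed both ways. PIFI also missed the threshold with median centring (0.56 log2), with a trended and robust variance model (0.56 log2), and without WT sample 4 (0.56 log2) or stn7 sample 6 (0.53 log2). The adjusted p in these 4 cases lay between 0.0515 and 0.0591, and with the replicate block it was 0.0719 (limma). After set centring PIFI (0.39 log2, SE 0.16), AT5G55580 (0.41 log2, SE 0.15), FBN2 (-0.50 log2, SE 0.16) and AT2G17670 (0.52 log2, SE 0.19) did not pass. The differences before it were 0.56, 0.81, -0.67 and 1.09 log2. APS4 passed after set centring (-0.74 log2, adjusted p = 0.0292), as did the plastid ribosomal protein gene RPL5 (AT4G01310), at 0.70 log2 (adjusted p = 0.0375) against 0.33 before it. No list was called by camera, where the smallest adjusted p was 0.511 with the preset correlation and 0.796 with an estimated correlation. At an unadjusted p under 0.05 camera called 0 of the 9 lists with either correlation, and fry called 2 for change in 1 direction and 8 for change in either direction. After adjustment fry called 0 and 7. Fry does not compare a list with the rest of the array, where 1051 of 3248 features had an unadjusted limma p under 0.05. Its calls therefore do not set these lists apart from other features.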

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

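Alternatives on duplicate samples, averaged replicates left out, the floor, cyclic loess and the probe number were chosen after seeing the data. Of the 61 genes that the naming rule covers, none that passed, as reported or in the alternative, changed direction under any setting run. Against 494 features called and 162 at 2-fold, scaling, the dim filter, the variance model, the probe choice, the higher floor and cyclic loess stayed within 1.5 times, and leaving out 1 sample gave 419 to 493 (151 to 171 at 2-fold). An offset equal to the floor gave 482 (86 at 2-fold). The planned offset, the 5th percentile of the values, was 0 and was not run.

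Without 1 averaged replicate, counts were 45 (WT 1), 30 (WT 2), 272 (WT 3), 4 (stn7 1), 284 (stn7 2) and 218 (stn7 3), with 45, 30, 130, 4, 176 and 108 at 2-fold. Fewer replicates give less power, but each of these fits had the same number of replicates, so this number does not account for their range. At 2-fold the count without stn7 2 was above the 162 with all replicates. Taken as 12 separate samples 1283 features were called, and samples 2, 4 and 6 alone gave 308. The 1 sample whose source name says mutant gave 8, all at 2-fold, of which 2 were shared in the same direction with the 494; that fit assumes the lone sample varies like the WT.

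Set centring gave 182 (56 at 2-fold), set and block centring 257 (59). Neighbourhood centring over 3 positions and 1 block gave 589 (79), 6 and 1 550 (85), 6 and 2 454 (78), 12 and 2 424 (86), 12 and 15 236 (82), and 3 and 15 215 (65). So 2 of the 8 centrings raised the count, and the cause was not tested. Set-centred counts without 1 averaged replicate were 12 (WT 1), 22 (WT 2), 67 (WT 3), 77 (stn7 1), 108 (stn7 2) and 120 (stn7 3), with 12, 22, 44, 47, 69 and 42 at 2-fold.

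Same-numbered averaged replicates correlated at 0.171, 0.120 and 0.0901, each best with its own number, but not all over 0.1. The replicate block gave 407 and ended the calls of 6 named genes (AT2G26110, FBN2, AT3G20680, CSLA01, PIFI and PSB27), with set centring 117 (43 at 2-fold) and on 12 separate samples 1442. Camera called 0 lists under every setting it was run on. Fry, run only with the settings of the report, called 0 directionally and 7 for change in either direction, without comparing a list with the rest of the array. STN7 is on no probe with an annotation entry. Signal over background is not known.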

Other observations

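The tests of the probe-number sets, of set centring and of consecutive samples were chosen only after the result had been seen, and the counts over other splits were planned. Of the 108 named genes called, 29 passed again under both set centring and set and block centring, 7 higher and 22 lower. Some of them lie outside the rule for named genes and were chosen after their values were seen. XERICO, a RING finger gene linked to abscisic acid, fell by 0.84 log2 (SE 0.15, adjusted p = 0.0174) and by 0.67 after set centring (adjusted p = 0.0440). AT2G39000 fell by 1.70 log2 (SE 0.14, adjusted p = 0.00344) and by 1.24 after set centring. AT3G52550 rose by 1.35 log2 (SE 0.31, adjusted p = 0.0293) and by 1.73 after set centring. Levels of AT2G39000 and AT3G52550 lay in the lowest 25% of the array.

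The differences between stn7 and WT followed the probe number. Print sets or positions on the arrays may be the source of deviations among replicates of 1 genotype, where the sets accounted for at least 4.73% of the variance, against at most 1.06% over 100 random renumberings. The set medians as the whole cause of the calls are argued against by 152 calls that passed again in the same direction once these medians were subtracted. For the set medians of stn7 minus WT, a genotype response of genes numbered together and a position effect cannot be told apart. Replicates of a group deviated from its mean by up to 0.449 in the sets above 0.4, but in 0 of 9 sets beyond 0.4 as far as the groups differed. That mean contains the replicate, so this measure understates the spread between replicates. In set 23 WT replicates 1 and 3 lay at 0.454 and -0.442, farther apart than the groups (-0.494). Replicates of a group were also farther apart than the groups in sets 34 and 43, but not in the rest of the 9. Finer structure stays open too, since differences still correlated after set centring at 0.15 for probes 6 numbers apart (0.33 before), 0.10 over the cycle (0.43) and 0.09 for neighbours (0.42), and the layout is not given in the sources used here.

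Consecutive samples deviated together in 12 of 12 samples, as duplicate readings of 1 array or RNA would. Separate plants handled together cannot be told apart from that, since both predict the consensus correlation of 0.669 and the labels name neither. The pair of stn7 samples 1 and 2 deviated together least, at 0.188, and its samples carried different source names. Those names, if right, go against 1 array or RNA for this pair. No biological explanation was tested. With 12 samples and consecutive ones as a random block, 671 features were called, 310 higher and 361 lower.

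In 1 of the 10 splits of the 6 averaged replicates into 3 and 3, the real one, 494 features were called, and the highest of the other splits gave 0. For the 2-fold count, 1 of 10 splits gave as many as 162, and the highest other gave 0. For gene lists, 10 of 10 splits gave as many as the 0 of the real one, and the highest other gave 0. No split can give fewer than 0, so this comparison was bound to come out so and decides nothing. With 10 splits no share under 0.05 can be reached.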
